A study of Mus musculus with 2 samples.

How the data were processed

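Total RNA of sorted Lgr5-GFP-positive intestinal stem cells was profiled on 2 Affymetrix Clariom D mouse arrays, 1 of circPan3+/+ and 1 of circPan3-/- cells; whether a sample came from 1 mouse or a pool is not given in the sources used here. Per the submitters' processing notes, the authors used Affymetrix Power Tools and RMA (background correction, normalization and median polish of probes into 1 value per transcript cluster); versions and genome build are not given in the sources used here. The deposited values are on a log2 scale, from -0.18 to 13.07; that base was taken from their range and from what RMA gives, because the table states no unit. They are single-channel levels, not centred per gene. RMA subtracts no GC-dependent background, and rows of background probes span a wide range of levels, so a low value does not by itself tell expression from background.

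The 2 deposited columns did not have the same distribution. Their medians were 2.51 and 2.62, and the median difference over all rows was 0.19. In addition, 69.1% of the rows of the circPan3+/+ column held a value that another row also held, against 4.20% of the circPan3-/- column (exact equality as deposited). The most frequent value of the circPan3+/+ column, 1.09, stood in 3702 rows. Whether the 2 arrays were scanned and processed alike is therefore not known, and every difference given here includes any effect of that; the scanner files were not used here.

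Rows were named from the platform's annotation of the probe identifiers, updated to current symbols through Entrez identifiers and synonyms in the RefSeq gene table (GRCm38.p6). Of 72688 rows, 65956 were transcript clusters and 6732 controls. There were 31271 rows with 1 symbol, 1479 with several genes, which were not named, and 33206 clusters with none. A gene with several rows was represented by the brightest (441 symbols). No genome coordinates are given because the table's build is not stated. Predicted models, long noncoding RNAs and small RNAs were kept apart from the other, named genes.

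The following choices were made before the data were examined. With 1 array per genotype there is no spread between samples and no test across samples, so genes were described by a rule of size, a difference of at least 2-fold, among named genes whose mean over both arrays was at or above the median of all rows (2.53). That left 14614 of 19692 named genes. For each of 36 gene lists (11 main and 25 supporting), the median difference over the measured members past this filter was placed among 10000 random lists of the same size, drawn from the named genes in the same 20 bins of mean level. A list was said to stand apart when it had at least 5 members measured and its median lay outside the central 95% of the random lists. About 1 in 20 lists of randomly drawn genes does so, but members of a real list can vary together. The place among random lists describes the 2 arrays and is not a p-value. Because random lists carry the shift of named genes, list results are relative to it. The genes named in the text were taken from the 10 furthest apart in each direction, up to 2 members in each direction of each list, the 3 furthest microRNA precursors and small nucleolar RNAs in each direction, and Pan3, Il13ra1, Il13ra2, Il4ra, Stat6, Foxp1, Ctnnb1, Lgr5, Olfm4 and Ascl2; of the list members and small RNAs that this rule gave, not every one is named. Muc2, Smoc2, Prom1, Sox9, Fstl1 and Slc14a1, and the genes named only in the closing section, were chosen after their values were seen.

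No detection calls were used here. As a limit, the 95th percentile of the rows named as negative controls was taken on each array, a choice made after seeing the data. Where the dimmer of a gene's 2 values lay under its array's limit, the fold is given as a bound, from the brighter value to that limit; where both did, or where the brighter value did not exceed that limit, values are given with no fold. Counts with bounds keep a gene only if its fold or bound is at least 2. They were added after seeing the data. They favour higher genes, because the limit was lower on the circPan3+/+ array and the shift of named genes was kept. Alternatives were centring of the differences, loess on mean level (span 0.3), quantile normalization, no filter or a filter at the upper quartile, the mean of all rows of a symbol, a threshold of 1.5-fold, list means, random lists from all single-symbol genes, and 50 bins. Added after seeing the data were a filter at the negative control limit, the use only of genes with values shared with no other row, and lists without shared members.

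The functions were tested on simulated differences for the same 14614 genes, with the observed shift and a spread taken from the interquartile range. Of 100 genes raised and 100 lowered by 1.5 (log2), 99% and 59% were past 2-fold, the gap coming from the shift that was simulated, and at 3 (log2) all were. Of the simulated genes left unchanged, 1091 were past 2-fold, against the 1416 higher and 400 lower ones observed; the spread was taken from all observed differences, which may hold real ones, so this is not an estimate of how many are due to noise. Lists of 15 genes stood apart in 5.5% of 200 draws with no shift, 91.5% with a shift of 0.5 and 100% with a shift of 1. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.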

Results

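Transcript levels were measured in intestinal stem cells of the mouse small intestine that carry or lack circPan3, a circular RNA named after its host gene Pan3. The cells came from 8-week-old Lgr5-GFP-CreERT2 mice, in which green fluorescent protein marks cells that express the stem cell receptor gene Lgr5, and GFP-positive cells were enriched by flow sorting from crypts. Total RNA was hybridised to the Affymetrix Clariom D mouse array, which carries probes for coding and noncoding transcripts. There was 1 array of circPan3+/+ cells and 1 array of circPan3-/- cells, so no difference below has an error or a p-value, and each compares these 2 arrays and not the genotypes. All differences are given as circPan3-/- minus circPan3+/+ on the log2 scale of the deposited RMA signal, a base taken from the range of the values because the table states no unit. They include a shift of named genes towards higher values on the circPan3-/- array, with a median of 0.36, and are best read against it. This shift was not common to all rows: the median was 0.57 in positive control rows and 0.27 in negative control rows. It was 0.11 in external spike-in rows and 0.09 in the 8 hybridisation and polyA control rows. Whether the shift is technical or lies in the RNA itself was not tested. The table held 72688 rows, with a median of 2.51 on the circPan3+/+ array and 2.62 on the circPan3-/- array. The values of rows named as negative controls reached a 95th percentile of 5.06 on the circPan3+/+ array and 5.56 on the circPan3-/- array, and levels below these limits lay within the range of those controls. On the circPan3+/+ array 69.1% of rows held a value that another row also held, against 4.20% on the circPan3-/- array, so it is not known whether the 2 arrays were scanned and processed alike, and the differences include any effect of that. The precision is limited by the number of arrays.

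Pan3, the host gene, had a signal of 4.84 in circPan3+/+ and 5.64 in circPan3-/- cells, a difference of 0.80, or 0.44 beyond the median of all genes, with the circPan3+/+ value under the control limit. The table holds 1 value for the whole Pan3 transcript cluster, with no reading of the circle, so it does not check the deletion. The circPan3+/+ value of Pan3 stood in 143 rows of the table.

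The first question was which transcripts differed in stem cells without the circular RNA. The gene furthest below its wild-type level with a signal above the control limit on both arrays was Il13ra1, which encodes a subunit of the receptor for interleukin 13 and interleukin 4. Il13ra1 had a signal of 11.97 in circPan3+/+ and 7.78 in circPan3-/- cells, a difference of -4.19 or 18.3-fold. Lgr5 itself followed, with 10.91 against 7.02, a difference of -3.89 or 14.8-fold. At the other end stood the gasdermin C genes, which encode pore-forming proteins: Gsdmc4 had signals of 4.67 in circPan3+/+ and 9.17 in circPan3-/- cells, Gsdmc2 of 3.87 and 8.43, and Gsdmc3 of 3.39 and 8.30. Because their circPan3+/+ values lay under the control limit, these are given as bounds of at least 17.2-fold, at least 10.3-fold and at least 9.46-fold, respectively. The Gsdmc genes are close paralogs, and probes may be shared between them.

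The 10 genes with the lowest differences ran from the neutrophil collagenase gene Mmp8, with signals of 7.88 in circPan3+/+ and 1.89 in circPan3-/- cells, to Serpinb2 at -4.17. Among them were the chemokine genes Ccl2 at -4.96 and Pf4 at -4.27, the C-type lectin gene Clec4n at -4.50, and the serum amyloid gene Saa3 at -4.81. The matrix metalloproteinase gene Mmp10 stood at -4.27, the haem oxygenase gene Hmox1 at -4.35 and Anxa10 at -4.87. Of these 10, only Il13ra1 was above the control limit in circPan3-/- cells, so the other fold differences are bounds, from at least 1.14-fold for Serpinb2 to at least 6.79-fold for Hmox1. The 10 genes with the highest differences held, besides the 3 gasdermin genes, the lipase gene Pnliprp2 at 3.72, the mucosal chemokine gene Ccl28 at 3.69, the fatty acid transporter gene Slc27a2 at 3.66, and the kallikrein gene Klk1b5 at 3.60. The phospholipase gene Pla2g4c at 3.55, Elapor1 at 3.49 and the defensin pseudogene Defa-ps16 at 3.45 completed them. The 10 were under the control limit in circPan3+/+ cells, with bounds from at least 2.24-fold for Defa-ps16 upwards. Klk1b5 and Defa-ps16 belong to families of near-identical copies.

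Of 14614 named genes past the filter on low levels, 1416 were at least 2-fold higher and 400 at least 2-fold lower in circPan3-/- cells. This split depended on the shift of named genes, which was larger in bright genes, with 0.19 in the dimmest eighth and 0.53 in the brightest eighth. Relative to the median of 0.36, 563 genes were at least 2-fold higher and 726 at least 2-fold lower, so that the share of higher genes among those apart was 78.0% as deposited and 43.7% after centring. It was 41.2% after loess on level and 49.2% after quantile normalization. Genes simulated with no difference of their own, but with this shift and the spread of all differences, were at least 2-fold apart in 1091 cases. That spread was taken from the observed differences themselves, so the simulation cannot tell how many of the counted genes are apart by noise. Both values lay under the control limits in 675 of the 1416 higher and 174 of the 400 lower genes, and the dimmer one alone in 337 and 185. Where a value under its limit gives only a bound, 541 genes were at least 2-fold higher and 78 lower. Such counts are called counts with bounds below. A difference followed by "at least" is bounded in this way, and "no fold" marks a gene for which the limits allow none. Counts with bounds favour higher genes. Where the dimmer value is under its limit, a higher gene is measured from 5.06 (circPan3+/+) and a lower one from 5.56 (circPan3-/-). The shift of named genes was not removed from them either. Pearson's r between the arrays across the 14614 genes, which are not independent replicates, was 0.90.

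**Figure D1:**
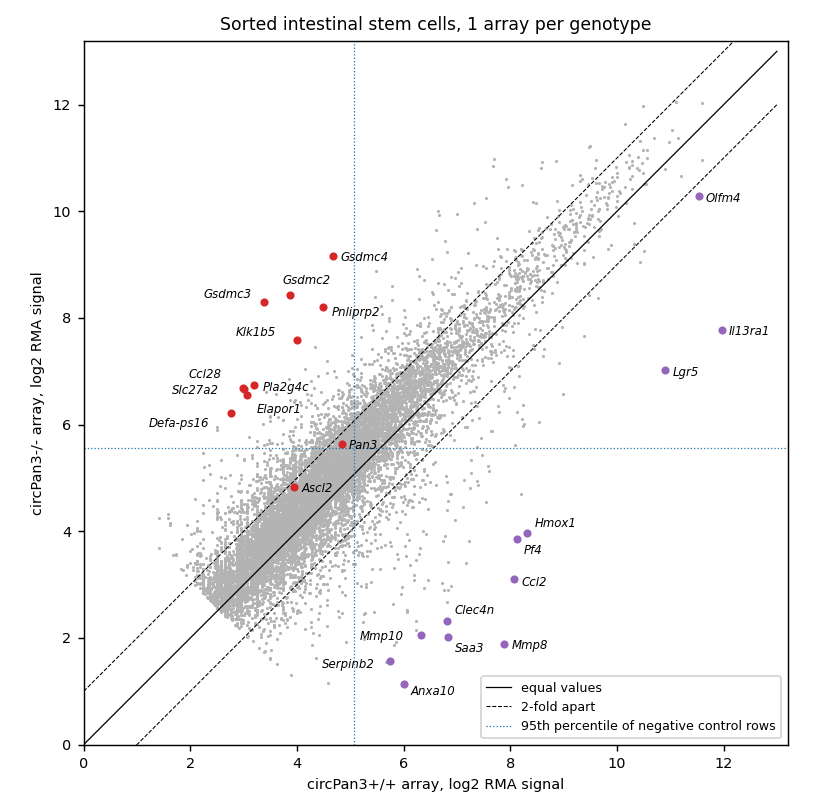
Each grey point is a named gene past the filter on low levels, with its log2 RMA signal on the circPan3+/+ array (x axis) and on the circPan3-/- array (y axis). Coloured points are the 10 genes furthest apart in each direction and Lgr5, Olfm4, Ascl2 and Pan3. Red marks higher and purple lower values in circPan3-/- cells. Il13ra1 and Lgr5 lie far below the 2-fold line at signals of 7.78 and 7.02 on the circPan3-/- array, and the Gsdmc genes lie far above it.

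Genes of the deadenylation machinery, to which the PAN2-PAN3 complex belongs, had a median of 0.80 over 15 members, at percentile 98.9 of matched random lists. That median equalled the difference of Pan3 itself, whose circPan3+/+ value was under the control limit. Of the 15, 5 were at least 2-fold higher as deposited (3 with bounds) but 0 after centring or loess, and 0 were lower as deposited. Cnot7 at 1.17 (at least 1.69-fold) and Parn at 1.14 (no fold) were the furthest above and Tob2 at -0.03 (no fold) the lowest. Regulators of mRNA binding and stability had a median of 0.80 at percentile 99.1, with 2 of 14 at least 2-fold higher as deposited and 0 after centring or loess, Zfp36 at 1.30 and Hnrnpd at 1.03.

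The second question was whether receptor signalling by interleukin 4 and interleukin 13 differed as a group. Of 11 measured members, Il13ra1 was the only one at least 2-fold apart as deposited, and the list median of 0.32 lay within the range of matched random lists, 0.15 to 0.83. Il4ra, the partner chain of Il13ra1, had a difference of -0.55, which was -0.91 after centring and -1.09 after loess, past 2-fold. Stat6, the transcription factor downstream of the receptor, had 0.32 and Foxp1, a forkhead transcription factor gene, 0.57 (no fold). Socs1, a feedback inhibitor, stood at 0.81 (no fold) and the adaptor gene Irs2 at 0.75. Il13ra2, the decoy receptor gene, had signals of 1.41 and 1.32, both under the control limits. The mean of the list, unlike its median, was below 0 at -0.12, and by the mean the list lay below the random range. That mean includes Il13ra1 at -4.19, while the other members ran from -0.55 to 0.81, so it does not show a lower group. Genes of epithelial responses to type 2 cytokines had a median of 0.91 over 10 members at percentile 99.9, with 5 at least 2-fold higher (3 with bounds). Ang4 at 3.37, an antimicrobial ribonuclease gene, and Clca1 at 3.27, a goblet cell secreted protease gene, led them. All 5 also stand in the Paneth, goblet or tuft list, and no member outside those lists was at least 2-fold higher. The call therefore does not separate a type 2 response from the difference in those markers. Arg1, an arginase gene of macrophages, was the single member at least 2-fold lower as deposited, at -3.01 (at least 1.33-fold), and the cytokine gene Il25 had 2.98 on both arrays.

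The third question was whether the stem cell programme as a whole was lower along with Lgr5. Of 29 measured genes of the Lgr5 stem cell signature, 13 were at least 2-fold higher, 4 at least 2-fold lower and 12 neither, and 14 had both values under the control limits. With bounds, 5 were at least 2-fold higher and 2 lower. The list median was 0.89, against 0.19 to 0.60 in the central 95% of matched random lists. Besides Lgr5, the lower members were Olfm4, a secreted stem cell marker, at -1.25 or 2.38-fold, Fstl1 at -1.20 and Slc14a1 at -1.01, and the circPan3-/- values of Fstl1 and Slc14a1 lay under the control limit. The ion cotransporter gene Slc12a2 stood highest at 2.93, with 5.47 against 8.39. Smoc2 had a difference of 1.94 between values under the limits, Prom1 1.80 (at least 2.85-fold), Axin2 1.72 (at least 1.88-fold) and Sox9 1.37. Ascl2, a transcription factor of crypt base stem cells, had 3.95 and 4.83, a difference of 0.89 with both values under the control limits. Rnf32 differed by 2.51, also between values under the limits. Of the 11 members other than Lgr5 with a mean level above the control limit, 6 were at least 2-fold higher and 1 lower, and their median of 1.34 stood at percentile 99.99 of matched random lists. With a limit on the circPan3+/+ array alone, 9 members were left, 3 higher and 3 lower, and their median of 0.19 lay within the range of such lists, -0.15 to 0.74. The 7 members above the limit on both arrays had a median of 0.58. When only genes whose values were shared with no other row were kept, the median of the signature no longer lay outside the random range, at 0.21 above the random median (percentile 88.8).

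**Figure D2:**
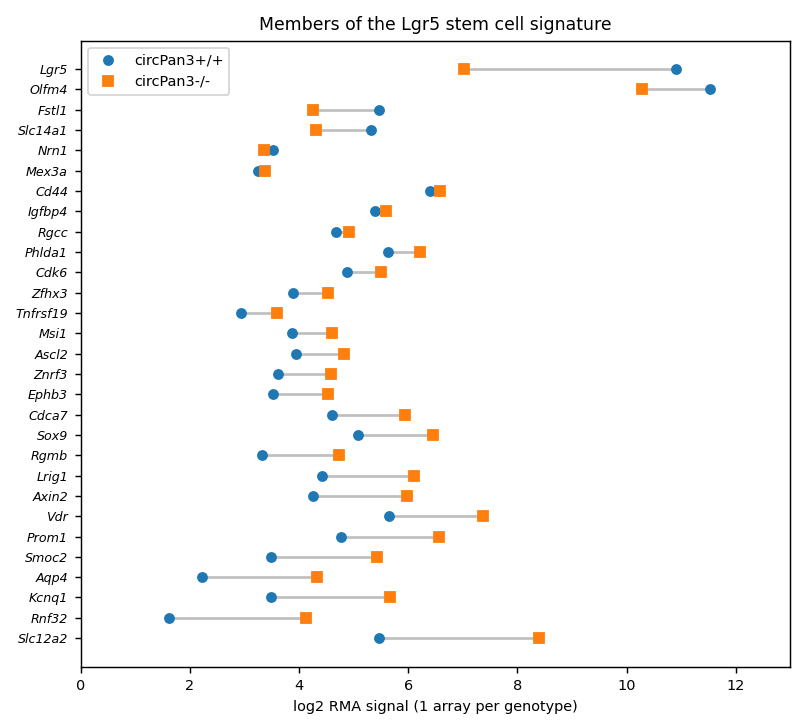
The log2 RMA signal (x axis) of each measured member of the Lgr5 stem cell signature (y axis, ordered by difference) on the circPan3+/+ array (circles) and the circPan3-/- array (squares), joined by a line. Lgr5 and Olfm4 have lower signals in circPan3-/- cells, while Slc12a2, Smoc2, Prom1 and Axin2 have higher ones.

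Wnt target and feedback genes had a median of 0.65 at percentile 98.9, with 4 of 17 members at least 2-fold higher (2 after loess, 2 with bounds) and Lgr5 alone at least 2-fold lower. Mmp7 at 1.89, a metalloproteinase gene of Paneth cells, and Axin2 at 1.72 (at least 1.88-fold), a feedback inhibitor of the pathway, were highest, and Lef1 had -0.55 (no fold). Without the genes that also stand in the stem cell signature, the median lay 0.12 above that of random lists, at percentile 78.6 and within their range. Machinery of the Wnt pathway lay within the random range with a median of 0.57, with Csnk1a1 at 1.49 and Fzd5 at 1.38. Ctnnb1 is annotated to a cluster shared with a microRNA gene and is not given. Cell cycle genes had a median of 0.75 against 0.27 to 0.67 in random lists. Of 32 members, 10 were at least 2-fold higher as deposited (7 with bounds), 4 after centring and 3 after loess; Ccnb2 stood at 1.90 and the proliferation marker Mki67 at 1.88, and 0 members were at least 2-fold lower as deposited.

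Secretory lineage genes were higher and enterocyte genes lower in circPan3-/- cells. Goblet cell markers had a median of 2.00 over 16 members, against 0.22 to 0.76 in random lists, with 13 at least 2-fold higher (8 with bounds), 3 neither and 0 lower. Klk1 stood at 3.40, Clca1 at 3.27, and the gene of the main intestinal mucin, Muc2, at 3.04. Paneth cell markers had a median of 1.72, with 11 of 13 at least 2-fold higher (10 with bounds), among them Ang4 and the phospholipase gene Pla2g2a at 3.12 (at least 5.28-fold), and with Guca2b at -0.38 and Lyz2 at -0.03. The defensin members are near-identical copies that probes may not tell apart. Enteroendocrine markers had a median of 0.95, with 9 of 18 at least 2-fold higher (4 after centring or loess, 4 with bounds) and 11 under the limits on both arrays, led by the hormone genes Gip at 2.63 (at least 1.92-fold) and Gcg at 2.10 (at least 2.06-fold). Tuft cell markers had a median of 0.87, with 4 of 11 at least 2-fold higher (1 with bounds). Of the 11, 9 lay under the control limits on both arrays, among them Rgs13 at 2.84 and Pou2f3 at 1.65. Enterocyte markers had a median of -0.38, against 0.22 to 0.70 in random lists, with 5 of 18 at least 2-fold lower (8 after loess) and 0 higher. The apolipoprotein gene Apoa4 stood at -2.50 and the fatty acid binding protein gene Fabp1 at -2.36 (at least 4.10-fold), while Vil1 had 0.32. Beside these lists, myeloid markers had a median of -1.52 and immediate early genes one of 1.55.

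The 6 lists of markers of cells other than epithelium had medians below the range of matched random lists, but many members lay under the control limits on both arrays, 13 of 18 in the T cell list and 6 of 7 in the neuron and glia list. Myeloid markers were furthest, with a median of -1.52 over 16 members and 11 at least 2-fold lower; 10 of the 11 were under the limit in circPan3-/- cells, and 4 were at least 2-fold lower with bounds. Among the 11 were S100a8 at -3.93 (at least 1.23-fold) and the macrophage gene Cd68 at -2.76 (at least 2.66-fold). Mcpt1, a mucosal mast cell protease gene, was the single one at least 2-fold higher, at 2.74, between values under the control limits, and Lyz2, which Paneth cells also can express, differed by -0.03. Markers of T cells, NK cells and innate lymphoid cells had a median of -0.40, with 4 of 18 at least 2-fold lower (6 after centring, 1 with bounds), including Klrd1 at -2.05 (no fold) and Il7r at -2.03 (at least 1.15-fold). Endothelial markers had a median of -0.31, with Emcn at -2.88 (at least 2.34-fold) and Kdr at -1.71 (at least 1.39-fold). B cell and plasma cell markers had -0.24, with 0 of 10 at least 2-fold apart as deposited and 2 lower after centring, and Cd79b at -0.85 (at least 1.08-fold). Enteric neuron and glia markers had -0.66, with 0 of 7 at least 2-fold apart as deposited and 4 lower after centring, and Gfap at -0.84 (no fold). Mesenchymal markers had a median of 0.01, below the random range of 0.09 to 0.64, and members went both ways: Sparc stood at -1.78 and Vim at -1.75, but the smooth muscle genes Acta2 at 1.49 (at least 2.42-fold) and Myh11 at 1.44 (no fold).

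Immediate early genes, which respond within minutes to tissue dissociation and other stimuli, had a median of 1.55, with 12 of 18 at least 2-fold higher (12 with bounds) and 0 lower; Fosb stood at 2.55 and Jun at 2.41. Interferon response genes had a median of -0.80, with 8 of 17 at least 2-fold lower as deposited but 1 with bounds, since all 8 were under the limit in circPan3-/- cells, with Ifit1 at -2.81 (no fold) and Rsad2 at -2.27 (at least 1.00-fold). Myeloid markers, at a median of -1.52, were lower on the same array. Antimicrobial and oxidant defence genes had a median of -0.38 but went both ways, with 2 higher and 2 lower by at least 2-fold with bounds. Reg1 stood at -3.40 (at least 2.42-fold) and Lcn2 at -1.40 (no fold) against Pigr, the receptor gene for secreted antibodies, at 2.51 and Reg4 at 1.63. MHC class II genes had a median of 1.11, with 5 of 7 at least 2-fold higher (2 after centring, 1 after loess and 3 with bounds), including H2-DMb1 at 1.71 (at least 1.95-fold) and H2-Ab1 at 1.39. BMP pathway genes had a median of 0.88, with 5 of 14 at least 2-fold higher (3 after centring, 2 after loess and 3 with bounds), among them Id1 at 2.14 and Bmpr1a at 1.53 (at least 2.53-fold). Nuclear-encoded oxidative phosphorylation genes had a median of 0.79, with 4 of 23 at least 2-fold higher as deposited, 1 after centring and 0 after loess, including Atp5o at 1.41. Glycolysis genes had a median of 0.11, below the random range of 0.20 to 0.84, with the glucose transporter gene Slc2a1 at -0.90 and Pfkp at 1.48 (at least 2.40-fold).

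The other 8 supporting lists tested lay within the range of matched random lists. Notch pathway and secretory precursor genes had a median of 0.50, with Atoh1, which specifies secretory cells, at 2.19 (at least 1.48-fold). Reserve stem cell and regeneration genes had 0.45, with Il1rn at -3.94 (at least 2.43-fold) and Anxa1 at -2.27 (at least 1.46-fold) against Ccn1 at 2.68. Heat shock and unfolded protein response genes had 0.65, p53 target and apoptosis genes 0.27, cholesterol synthesis genes 0.53, fatty acid oxidation genes 0.68 and cytoplasmic ribosomal protein genes 0.48. Cd36, a fatty acid receptor gene, stood apart from its list at -2.26 (at least 2.43-fold). Housekeeping genes had a median of 0.40, within the range as well. Red blood cell genes and histone genes had too few single-gene rows, 2 and 4. In all, 14 of 34 lists lay above and 10 below the central 95% of matched random lists, where lists of randomly drawn genes would place 1.7 outside. Members of a list can vary together, which random lists do not reproduce. More than 1.7 lists could therefore fall outside with no effect of the genotype. Several lists share genes, so the lists are not independent. The calls of tuft markers, BMP, oxidative phosphorylation, glycolysis, defence, deadenylation and mRNA stability genes each ended under at least 1 other setting, as did those of the stem cell signature and of Wnt targets.

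**Figure D3:**
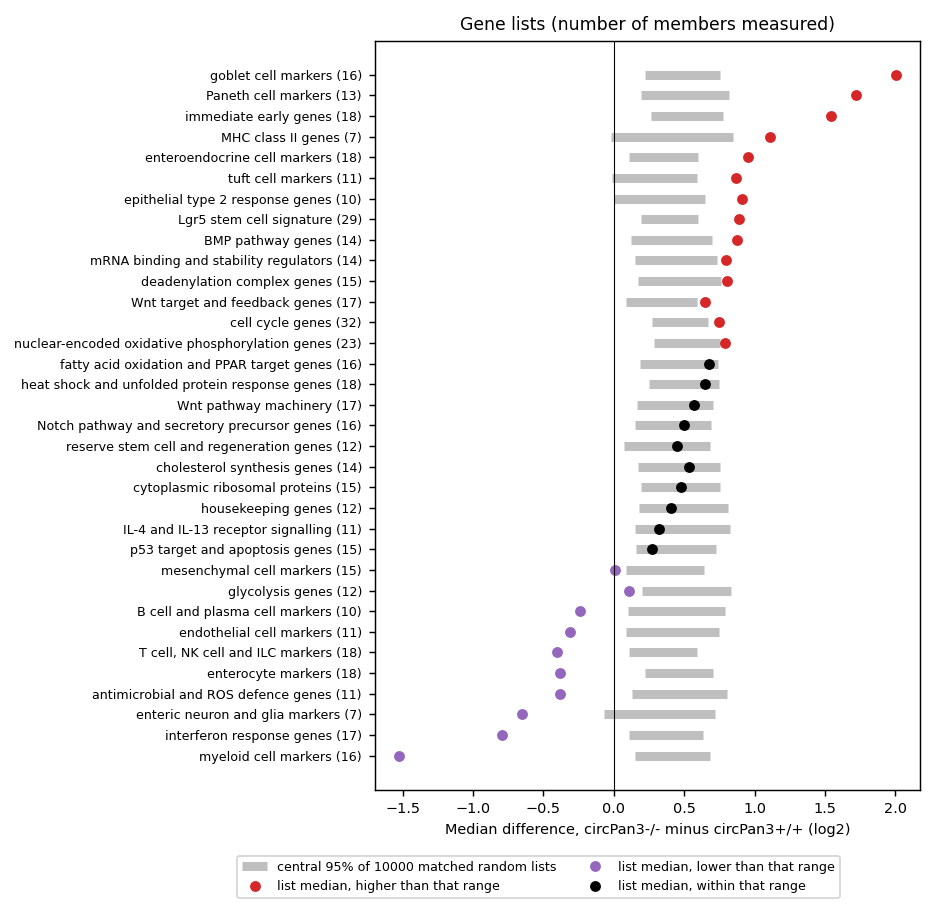
For each gene list fixed in advance (y axis, number of measured members in parentheses), the point is the median difference between the circPan3-/- and circPan3+/+ arrays in log2 units (x axis) and the grey bar the central 95% of 10000 matched random lists. Goblet and Paneth markers, at 2.00 and 1.72, lie furthest above the bars, and myeloid markers, at -1.52, furthest below.

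The array also measured noncoding RNA. Small nucleolar RNAs had a median difference of -0.46 over 64 genes, with 14 at least 2-fold lower and 5 higher (11 and 4 with bounds). Snora69 was the lowest at -3.06 (at least 6.51-fold), with Snord111 at -2.04 (at least 2.45-fold) next, and Snord45b the highest at 1.69, with Snora73b at 1.39. MicroRNA precursors had a median of 0.27 over 447 genes, against 0.36 in named genes, with 25 at least 2-fold higher and 11 lower (3 and 5 with bounds). Mir5124a had signals of 3.59 and 7.16, at least 4.29-fold higher, and Mir466k stood at -1.88 (at least 2.30-fold) and Mir669m-2 at -1.77. Mir466 and Mir669 belong to families of near-identical copies, and a precursor's value does not give the level of the mature microRNA. Other small RNAs, mostly copies of 5S ribosomal RNA and spliceosomal RNA, had a median of -1.34, with 67 of 96 at least 2-fold lower (62 with bounds) and 0 higher. Predicted gene models and long noncoding RNAs had a median of 0.16 over 4870 genes, with 265 at least 2-fold higher and 251 lower (76 and 93 with bounds). Of 11700 transcript clusters with no gene symbol, 1286 were at least 2-fold higher and 405 lower. Rows of the mitochondrial genome had a median difference of -0.21 over 30 rows.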

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

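The tests on abundant macrophage transcripts and on unshared values were chosen after the arrays had been examined but before their values were seen, and the other tests in this part after their results were seen. Signals also stood in rows that the gene comparisons do not use. Among transcript clusters annotated to several genes, 84 of 921 were at least 2-fold higher in circPan3-/- cells and 64 lower. Among 11700 clusters with no gene symbol, 1286 were at least 2-fold higher and 405 lower. Of the 14614 named genes, 1416 were higher and 400 lower. All these counts are as deposited, with the shift towards higher values kept.

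Lgr5 was 14.8-fold lower in circPan3-/- cells while the median of its signature was not lower. Fewer stem cells in the knockout sort would lower the other members too, and this stays open. The 11 with a mean level above the control limit had a median 0.83 above that of matched random lists. With a limit on the wild-type array alone 9 were left, and their median stood at -0.17 relative to such lists, within their range. That limit removes members that rose from under it, such as Prom1 (at least 2.85-fold). It keeps members that fell under the limit of the other array, such as Fstl1 (-1.20). The 7 above the limit on both arrays had a median of 0.58 as deposited. Other crypt cells also express many of these genes, such as Slc12a2 (2.93), and Olfm4 was lower (-1.25). The shift by level does not account for the lower Lgr5 and Il13ra1 values, because it was upward. Its median was 0.19 in the dimmest and 0.53 in the brightest genes. A loess fit on level subtracts this shift, so it could only move these differences further from 0. After loess, the one nearer to 0 was -4.41, which is therefore no test of scaling. Other differences in how the arrays were scanned or processed stay open. Signal of single probes in these clusters stays open, because the table holds 1 row per gene and no values of single probes, and so does an effect of the circular RNA, which was not tested, since genotype and array cannot be told apart with 1 array each.

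Myeloid genes were lower in circPan3-/- cells, where 10 of the 11 markers at least 2-fold lower lay under the control limit. A candidate explanation is that more macrophages or other myeloid cells passed the wild-type sort. The 27 measured abundant macrophage transcripts, fixed apart from the marker list, had a median that stood at -1.18 relative to random lists. Of them, 24 lay at least 0.5 below the median of all genes, with Fcgr3 (at least 2.51-fold lower), Cybb (at least 3.25-fold) and Ctss (-1.36). None of these transcripts stands in a list fixed in advance, while Clec7a and Ms4a7 also stand in gene families chosen later. Epithelium also expresses some, such as Lgals3 (-0.13), Cst3 (-0.37) and Cyba (-0.48). Other white blood cells also express several, such as Cd53 (-1.86) and Coro1a (-0.13). The list therefore does not tell macrophages from neutrophils or monocytes. The GFP gate should remove macrophages. More cells of every non-epithelial type stays open as well. Among markers with a mean level above the control limit, the 19 of other types lay 0.83 above the 7 myeloid ones relative to random lists. Of these 19, 6 were at least 2-fold lower. The gap was under the myeloid interquartile range (1.45), but that is a spread of single genes and not the error of a median, so it cannot decide. Lists with enough members stood from -0.84 (B cell) to -2.07 (myeloid), a range of 1.23, over the 0.5 set for an equal rise of every type. Emcn (at least 2.34-fold) and Vim (-1.75) were lower, but 0 of 5 B cell markers were lower by 2-fold and Acta2 was higher (at least 2.42-fold). A genotype effect on inflammation in the tissue stays open and was not tested.

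Secretory genes were higher and enterocyte genes lower in circPan3-/- cells. A larger epithelial share in the knockout sort cannot account for both, because enterocyte markers stood at -0.84 relative to matched random lists; it stays open for part of the secretory difference, since pan-epithelial genes such as Epcam (1.14) and Cdh1 (1.16) had a median 0.41 above random lists. Repeated values of the wild-type array were argued against as the source of these calls. All 3 of 3 lists (goblet, Paneth and enterocyte) kept their call among genes with unshared values. Those values come from the same array, so other differences in scanning or processing stay open. Another mix of epithelial cell types in the sorts is consistent with 27 of 29 goblet and Paneth members (93.1%) lying above the median of all genes, a value that largely restates the pattern. It was not separated from a genotype effect on differentiation or from differences in dissociation, where immediate early genes differed as well.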

How the results depend on the processing

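No paired analysis was possible because each genotype has 1 array, and for the same reason no replicate could be left out; no value here has a replicate check. The filter at the negative control limit, the unshared values and the lists without shared members were chosen after seeing the data. The counts of genes at least 2-fold higher and lower (1416 and 400) depended on the scaling: 563 and 726 after centring, 504 and 720 after loess, and 630 and 651 after quantile normalization. Filters also moved them: at the upper quartile of level 254 were lower, above the negative control limit 626 were higher and 119 lower, and with unshared values 622 were higher and 248 lower, in each case among fewer genes. At 1.5-fold they were 4433 and 812. Of the 34 lists, 20 kept their call under every alternative run, of which centring cannot move a list's place among random lists, and the other changes are given as the excess over the random median. Wnt target genes lay within the random range with 0.22 by the mean of rows, 0.078 by the list mean, 0.031 above the control limit, 0.18 with unshared values and 0.12 without stem cell members. With unshared values, where fewer members were left, the stem cell signature (0.21), tuft markers (0.28), BMP genes (0.37) and mRNA stability regulators (0.40) also lay within it, and reserve stem cell and regeneration genes, within the range in the main setting (0.07), lay below it at -1.04. The mRNA stability regulators also did so at the upper quartile (0.31), by the mean (0.31) and above the control limit (0.28), where deadenylation genes (0.33) and defence genes (-0.046) did too. By the list mean, Wnt machinery (0.30) and IL-4 and IL-13 signalling (-0.59) came to stand apart, while oxidative phosphorylation (0.22) and glycolysis (-0.38) no longer did. The mean of IL-4 and IL-13 signalling includes Il13ra1 at -4.19, while its other members ran from -0.55 to 0.81. Against random lists of all single-symbol genes, heat shock (0.28) and fatty acid oxidation (0.28) came to stand apart and glycolysis (-0.26) did not. The causes of these changes were not tested. Under 5 members were left in 9 of the 34 lists above the control limit, in 3 with unshared values, in 1 at the upper quartile and in type 2 response genes without goblet, Paneth and tuft members, so these have no value there. Of 152 genes whose difference was recomputed under other scalings, 27 changed their side of 2-fold under some alternative and 0 of those past 2-fold changed sign. Besides the number of arrays, signal over the negative controls limits the values, with 675 of the higher and 174 of the lower genes under the limits on both arrays.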

Other observations

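All groups in this part were chosen after the data were examined, several because a member such as Mmp8, Ccl2, Clec4n or Gsdmc3 was among the genes furthest apart, and those genes are counted in them, so their place among random lists is no independent evidence. The families given as apart from matched random lists were so after loess and quantile normalization as well. Many of the lower ones are expressed in myeloid cells, whose markers had a median of -1.52 with 11 of 16 at least 2-fold lower, 4 of them when a value under the control limit gives only a bound (with bounds). Of 17 matrix metalloproteinase genes, 9 were at least 2-fold lower in circPan3-/- cells (2 with bounds) and 1, Mmp7, was higher; their median of -1.15 lay below 0.07 to 0.55 in matched random lists. Of 7 C-type lectin genes of the Clec4 and Clec7 groups, 5 were at least 2-fold lower (2 with bounds), with a median of -2.16, and of 13 Ms4a genes 5 were (1 with bounds), with Ms4a4a at least 2.30-fold lower. Of 29 CC and CXC chemokine genes, 7 were at least 2-fold lower and 3 higher as deposited, 9 and 1 after centring, 10 and 2 after loess, and 4 and 1 with bounds; their median was 0.03 as deposited and -0.33 after centring, and they ranged from Ccl2 at -4.96 (at least 5.71-fold) to Ccl28 at 3.69 (at least 3.07-fold). Glutathione S-transferase genes had a median of 0.02 over 18 members as deposited and -0.34 after centring, below their random range, with 4 at least 2-fold lower, also with bounds, and Gsta4 at -2.42 (at least 3.21-fold).

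On the other side, the 4 gasdermin C genes, too few for the comparison with random lists, were at least 2-fold higher, from Gsdmc at 2.27, between values under the control limits, to Gsdmc3 at 4.91 (at least 9.46-fold), as were 5 of 9 kallikrein 1 genes (2 with bounds) and 17 of 19 alpha defensin genes (15 after centring, 13 after loess, 17 with bounds). Members of these 3 families resemble one another in sequence, so their values are not independent. Solute carriers (299 genes), proteasome subunits (40), keratins (39) and cytochromes P450 (52) lay within the range of matched random lists. Zinc finger Zfp genes had a median of 0.20 over 303 genes as deposited and -0.15 after centring, just below their range of 0.23 to 0.34 as deposited, with 22 at least 2-fold higher and 0 lower as deposited (3 and 0 with bounds), 2 and 4 after centring, 3 and 1 after loess, and 3 and 3 after quantile normalization.

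The 2 columns differed in how their values repeat. The circPan3+/+ column held 24249 distinct values and the circPan3-/- column 70386 in 72688 rows, and between signals of 3 and 6 the share of rows with a repeated value was 61.7% against 2.95%. Smoc2, a stem cell marker, had a circPan3+/+ value that stood in 639 rows, while the circPan3+/+ values of Lgr5 and Il13ra1 each stood in 1 row.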
